A study of Mus musculus with 6 samples.

How the data were processed

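Total RNA of sorted genital tubercle cells had been labelled with biotin and hybridized to Affymetrix mouse arrays with 45101 probe sets, per the labels' protocols and the platform's probe table. The labels state dissection of the tubercle, trypsin dissociation and sorting for reporter fluorescence, with RNA from pools of 3, 5 and 2 littermates in each group. Cells had been sorted as reporter-positive or reporter-negative, and groups were taken from the sample labels alone. The labels do not say that the positive and the negative sample of equal pool size came from the same litter. Their titles carry adjacent numbers, so a shared pool is possible, but the main comparison had no block for it. Deviations from the group mean correlated across genes at 0.127, 0.033 and 0.109 between the positive and negative replicates 1, 2 and 3. Replicates of unlike number gave -0.131 to 0.063, so these values leave a shared pool open. The p-values measure the spread between arrays, 1 for each pool and fraction, so differences between pools and array noise are not told apart.

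The deposited values are 1 intensity per probe set and array. They are never negative, have 2 decimals and span several orders of magnitude, so they were read as a linear scale. GCOS, the scanner software of the manufacturer, is named in the submitters' processing notes for 1 of the 6 samples, without a version. The summarization algorithm, the target scaling and any filter are not given in the sources used here. Array medians differed many-fold while hybridization controls were alike, so the deposited intensity values had apparently not been scaled to a common level.

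From these values 64 control probe sets were set aside. Medians of log2(signal + 16) differed by 0.50 between arrays, over the limit of 0.2 fixed in advance, so the linear signals of the remaining 45037 probe sets were quantile normalized and then transformed to log2(signal + 16). Fold changes are on this scale, which understates changes of dim genes. Quantile normalization gives every array the same distribution, so it also stretches the noise of an array with little signal. The median absolute deviation from the negative mean was 0.94 in positive replicate 3 and 0.20 to 0.37 in the other arrays. The p-values of the 6 arrays include this spread. Of the 45037 probe sets 34945 had 1 gene, 932 had several and 9160 were unnamed here. Symbols were updated through gene identifiers in the RefSeq gene table of assembly GRCm38.p6, which matched 34741 of the 34945. No coordinates were used. For each of 18193 genes the probe set with the highest mean over all arrays was kept, and genes with a mean above the 30th percentile of named probe sets were tested, 14071 in the 6 arrays. The rule below named 67 genes, of which 42 had several probe sets and 19 had at least 1 probe set of opposite sign. Among the latter were Slc4a1, Tent5c, Csf1r, Frzb, Nrarp, Ptch1, Nid1 and Trp63.

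Groups were compared with lmFit and eBayes with an intensity trend in limma 3.58.1 (R 4.3.3), with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists were fixed from textbook knowledge before the data were examined: 27 lists with 498 genes, of which 470 had a probe set of their own and 424 were tested. The other list genes are not analysed here. Lists were tested with camera at a preset correlation of 0.01, then with an estimated correlation and with fry, adjusted over the lists. Genes named in the text were chosen by a rule fixed in advance: Shh, up to 12 genes per direction with the largest significant and non-overlapping change of at least 2-fold, and for each list up to 4 significant members plus up to 2 against the list's majority and 2 others with the largest change. Clone and model names were left out of the first 12. After the data were seen, the same rule was applied to the 5 arrays without positive replicate 3. Foxa2, Epcam, Cldn6, Esrp1, Grhl3, Sfn, Krt5, Krt10, Krt14, Krt17, C1qa, Foxf1, Pdgfra, Hoxd13 and Isl1, and genes named only in the closing section, were picked after their values were seen.

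Signal limits what each array can show. Background was taken as the brightest of 27 unspiked bacterial control probe sets on each array, 1.12 to 8.28 in deposited units, and hybridization controls were the mean of 18 probe sets. The steps were tested on simulated data, with values of 14071 genes drawn from the real means and the spread of each array and 200 genes changed in each of 20 draws. In the 6-array comparison of positive against negative cells, changes of 1, 2, 3 and 4 on the log2 scale were recovered in 4.7%, 78.6%, 97.3% and 99.7% of cases, with 0% false calls. In the 5-array comparison changes of 1 were recovered in 64.6% of cases and larger ones in 100%, with 5.72% false calls. All simulated genes of an array shared 1 spread, which real genes do not, so these shares may overstate the power in the real data. In the real 6 arrays Hbb-bh1 at -4.07 and Foxa1 at 3.81 did not pass. A simulated list moved by 1 was found in 100% of draws of either comparison, and an unmoved list in 5% of draws with 6 arrays and 10% with 5. Simulated genes varied independently, so these shares cannot tell how camera behaves where list members are correlated. In the real 6 arrays the estimated correlation was 0.427 for the mesenchymal list and 0.260 for the epithelial list.

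Alternatives chosen before the data were examined were the values without normalization, median centring, no filter or a filter at the 50th percentile, pseudocounts of 1 and 64, the mean of all probe sets of a gene or the most variable one, eBayes without trend or robust, a block for pool size, and leaving out each array or both arrays of a pool size. Alternatives chosen after seeing the data were scaling to a trimmed mean (2% trimmed at each end), array weights, and the block or the estimated correlation without positive replicate 3. Probe sets without a gene name were tested in the same way and are reported apart.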

Results

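The genital tubercle is the embryonic outgrowth that forms the penis or the clitoris, and the urethral plate is the sheet of epithelium along its midline. The arrays compared cells of tubercles at 12.5 days post coitum from mouse embryos in which Cre recombinase, made from the Shh locus, switches on a yellow fluorescent reporter. Fluorescence-activated sorting had given a reporter-positive fraction, which the series design describes as urethral epithelium that expresses Shh, and a reporter-negative fraction, the other cells of the tubercle. Each group held 3 arrays, and the labels give the tissue behind each array as a pool of littermates of both sexes, with 3, 5 and 2 embryos for replicates 1, 2 and 3 of either group. The question was which transcripts set the Shh-expressing epithelium apart from the rest of the tubercle.

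Transcript signal differed strongly between arrays. The median deposited signal of probe sets with a gene name was 7.62, 8.84 and 2.15 in negative replicates 1, 2 and 3 and 4.73, 3.56 and 0.34 in positive replicates 1, 2 and 3. Control transcripts added at hybridization averaged between 1443 and 1884 on every array, and positive replicate 3 had the highest value. In that array 24.6% of named probe sets exceeded the brightest unspiked control probe set, against 44.0% to 59.3% in the other 5. Its Spearman correlation with the other arrays, across probe sets, was 0.303 to 0.317, while the other 5 correlated at 0.671 to 0.822 among themselves. Probe sets are not independent replicates, and the number of arrays limits the precision of every comparison.

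**Figure D1:**
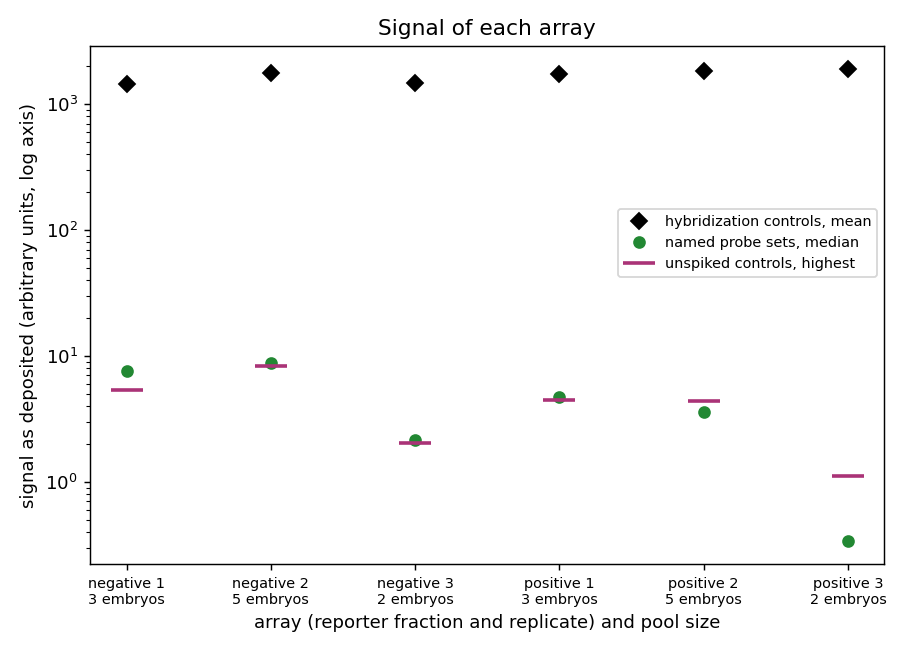
Deposited signal on a log axis (arbitrary units) for each array, with its reporter fraction, replicate and pool size on the horizontal axis. Diamonds are the mean of the hybridization controls (1443 to 1884), circles the median of named probe sets (8.84 at most, 0.34 in positive replicate 3) and bars the brightest unspiked control.

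Shh and Krt8 were higher in the reporter-positive cells. Shh, the secreted hedgehog ligand whose locus drives the reporter, had a normalized log2 signal of 9.40 ± 0.79 (SD, n = 3) in positive arrays and 4.37 ± 0.29 (SD, n = 3) in negative arrays. The difference was 5.03 (SE 0.47, adjusted p = 0.0122, limma with Benjamini-Hochberg adjustment), and after normalization Shh was higher in 3 of 3 positive arrays. The size of the difference varied from 2.77 to 7.11 over 23 alternatives. As deposited, the brighter Shh probe set read 287, 718 and 16.9 in positive replicates 1, 2 and 3. In the negative ones it read 1.31, 18.4 and 2.51, where the brightest unspiked control read 5.36, 8.28 and 2.03. Before normalization, positive replicate 3 thus lay below negative replicate 2. The dimmer Shh probe set read 5.12, 6.39 and 1.06 against 1.18, 1.49 and 1.05. Krt8, a keratin of simple epithelia, measured 9.09 ± 0.78 against 4.63 ± 0.11 (SD, n = 3 each), a log2 difference of 4.46 (SE 0.45, adjusted p = 0.0144, limma).

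Shh and Krt8 were the only 2 of 14071 genes past an adjusted p of 0.05 in the 6 arrays. Both differed by more than 2-fold, and no gene was significantly lower. At an unadjusted p under 0.05 limma counted 728 genes, 5.17% of those tested. The values of the groups did not overlap for 13.3% of genes, where chance gives 10%. Both calls were kept with a block for pool size over the 6 arrays (limma, lowest adjusted p = 0.0249). Both calls were lost when any of the 3 negative arrays was left out, and also with values as deposited, median centring, a pseudocount of 64 or the mean of probe sets. The adjusted p of Shh was then 0.0588, 0.0504 and 0.180 without negative replicates 1, 2 and 3 (limma, 9.25e-17 to 0.598 over 23 alternatives, past the threshold in 16).

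Without the dim array, positive replicate 3, many more epithelial genes passed. In the remaining 5 arrays 84 of 13960 genes differed (limma, adjusted p under 0.05), 77 higher and 7 lower in reporter-positive cells, and 80 of them by at least 2-fold. Other fits gave other counts. Array weights over the 6 arrays gave 255 higher and 225 lower genes (limma). A block for pool size without positive replicate 3 gave 283 and 279, but negative replicate 3 is then alone in its block and adds nothing to the difference. Both fits were chosen after seeing the data. The 4 arrays of replicates 1 and 2 gave 20 and 7 without a block. All 84 kept their sign in the 6 arrays, but those hold the same 5 arrays, so this adds no support. Shh and Krt8 were among the 84. Foxa1, a pioneer transcription factor of endodermal epithelia, had the highest log2 difference after these (SE 0.42, adjusted p = 0.000499, limma, and 2.01e-13 to 0.598 over 23 alternatives). Sox2, a progenitor transcription factor, differed by 2.86 (SE 0.31) and Foxa2 by 2.27 (SE 0.34). Among keratins, Krt18 differed by 3.30 (SE 0.38), Krt19 by 2.95 (SE 0.36) and Krt7 by 2.66 (SE 0.35). Cdh1, the epithelial cadherin, differed by 2.85 (SE 0.31), the desmosome protein Dsp by 2.58 (SE 0.46), the keratinocyte kinase Ripk4 by 2.63 (SE 0.41) and the annexins Anxa1 and Anxa8 by 2.78 (SE 0.33) and 2.46 (SE 0.43). In the 6 arrays the adjusted p of these 11 genes lay between 0.0626 for Foxa1 and 0.725 for Cdh1 (limma). The brightest probe set of each gene was chosen again for the 5 arrays, and for Anxa8 it was another one than in the 6. Anxa8 averaged 6.79 in the positive arrays of the 5-array fit. Its probe set in the 6-array fit read 4.86 and 6.04 in positive replicates 1 and 2.

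All 7 genes that were lower in those 5 arrays without a block for pool size are expressed in red blood cells. The embryonic globins Hbb-bh1, Hba-x and Hbb-y differed by -4.26 (SE 0.49), -3.40 (SE 0.53) and -1.44 (SE 0.24) on the log2 scale. Slc4a1, the anion exchanger of the red cell membrane, differed by -2.45 (SE 0.29), Alas2, which starts haem synthesis in erythroid cells, by -1.88 (SE 0.39), Bpgm, which makes 2,3-bisphosphoglycerate, by -1.72 (SE 0.34) and Tent5c by -2.06 (SE 0.41). One further probe set of Slc4a1 and one of Tent5c went the other way. All 3 positive arrays were below all 3 negative arrays for each of these 7 genes, but none passed in the 6 arrays, where the lowest adjusted p was 0.0626 (limma). Lower genes of other kinds passed in some alternatives. The collagen Col1a2, the mesenchymal cadherin Cdh11 and the patterning factor Tbx4 each passed in 3 of 23 (limma, lowest adjusted p = 0.000351, 0.00869 and 0.00201).

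**Figure D2:**
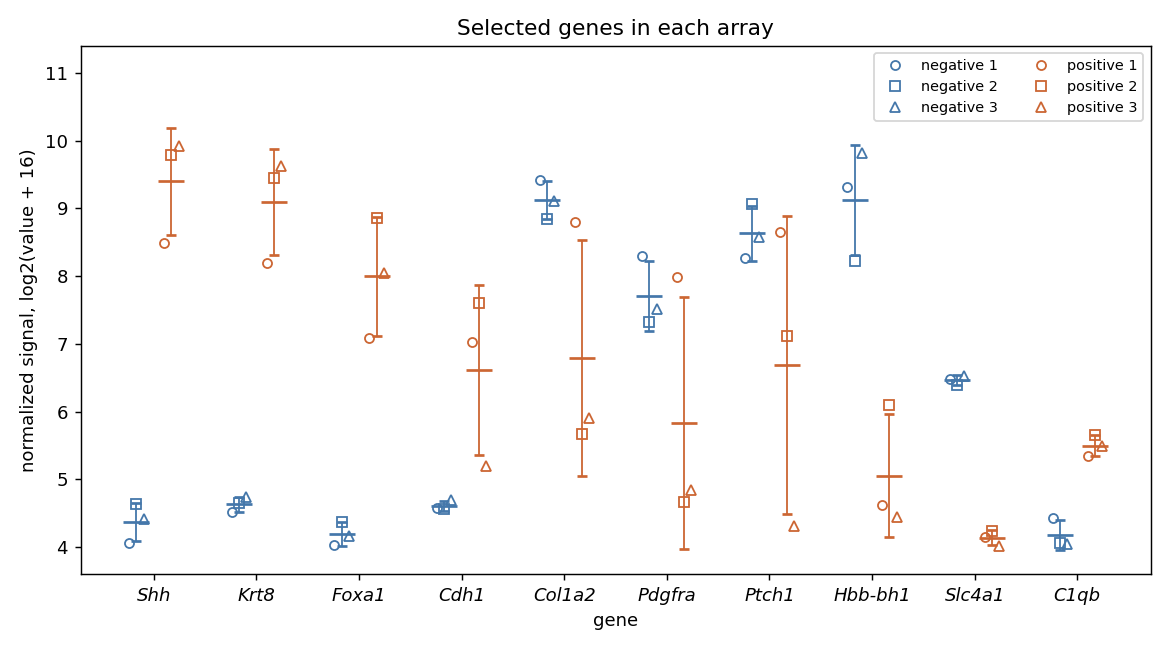
Normalized log2(signal + 16) of 10 genes (horizontal axis) in each array; open symbols are single arrays (circle, square and triangle for replicates 1, 2 and 3), dashes the mean of 3 arrays and bars the SD. Shh lies at 9.40 on average in positive arrays and 4.37 in negative ones, while Pdgfra in positive replicate 1 (7.98) lies within the negative range.

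Epithelial identity genes were higher in the reporter-positive cells as a group. Of 30 measured members 28 had a positive log2 difference and the median was 1.72, with 1 member past the threshold over all genes, Krt8, and 21 higher adjusted over the list alone. In the 5 arrays 15 of 29 members were higher over all genes, among them Epcam at 1.81 (SE 0.38), Cldn6 at 1.95 (SE 0.25) and Esrp1, a splicing regulator of epithelia, at 2.31 (SE 0.37). Camera with a preset correlation called the list (adjusted p = 7.00e-26), and the call was lost at adjusted p = 0.158 with an estimated correlation. Endodermal and urogenital epithelium genes were also higher by camera (adjusted p = 1.85e-10, and adjusted p = 0.158 with an estimated correlation). Of its 15 measured members 1 passed over all genes, Shh, and 6 passed adjusted over the list alone. The sort itself selects for Shh, so this member raises the list by design, and the list was not tested without it. In the 5 arrays 5 of 14 members passed, including Grhl3 at 1.92 (SE 0.26). Grhl3 was at 1.15 in the 6 arrays and did not pass there.

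Surface ectoderm genes and basement membrane genes were higher by camera, with both calls lost under an estimated correlation. The surface ectoderm and stratified epidermis list had a median of 0.26, with 8 of 12 members positive and array medians of 0.44, 0.58 and -0.23 in positive replicates 1, 2 and 3 against the negative mean. It had none past over all genes and 3 adjusted over the list alone (camera adjusted p = 0.0130, and adjusted p = 0.480 with an estimated correlation). Its largest differences were Krt15, a basal keratin, at 2.31 (SE 0.40) and Perp, a desmosome protein, at 1.58 (SE 0.46), neither past the threshold over all 14071 genes. The other measured keratins of the list, Krt5, Krt10, Krt14 and Krt17, differed by 0.11, -0.58, -0.57 and 0.39, and none passed. In the 5 arrays 3 of its 12 members passed, Krt15, Perp and Sfn. The list was not called by camera without positive replicate 1 (adjusted p = 0.151) or without positive replicate 2 (adjusted p = 0.173), and the range over 26 alternatives was 4.78e-06 to 0.480. Basement membrane and hemidesmosome genes had a median of 0.34 and 16 of 23 members positive (camera adjusted p = 0.00142, and adjusted p = 0.158 with an estimated correlation). The estimated correlation of this list was -0.033, below the preset 0.01, so correlation between its members does not account for that loss. The Wnt response list below, with an estimated correlation of 0.023, close to the preset, lost its call too. A call lost under an estimated correlation therefore does not by itself show that list members are correlated. None passed over all genes or adjusted over the list alone. Frem2, a protein of the epithelial basement membrane, measured 7.01 ± 1.30 against 4.65 ± 0.20 (SD, n = 3 each), and Nid1, a basement membrane linker that mesenchyme also makes, 5.14 ± 1.22 against 6.89 ± 0.30.

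Mesenchymal identity genes were lower in the reporter-positive group as a set, but not in every array. The list median was -0.74, and 5 of 32 members had a positive difference. None passed over all genes or adjusted over the list alone in either fit. Camera called the list (adjusted p = 3.94e-06), and the call was lost at adjusted p = 0.482 with an estimated correlation. Relative to the negative mean, the list median was -0.03 in positive replicate 1, -1.31 in replicate 2 and -0.95 in replicate 3. Col1a2, a fibrillar collagen, read 8.80, 5.68 and 5.90 in positive replicates 1, 2 and 3 against 9.13 ± 0.28 (SD, n = 3) in negative arrays. Cdh11, the mesenchymal cadherin, differed by -2.29 (SE 0.81, adjusted p = 0.725, limma).

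Hedgehog response genes were lower by camera in the cells that make the ligand (adjusted p = 0.000440, and adjusted p = 0.432 with an estimated correlation). The median over 12 members was -0.88, no member passed over all genes, and 2 were lower adjusted over the list alone, the mesenchymal transcription factors Foxf1 and Foxf2. Foxf2 measured 4.77 ± 0.75 against 6.50 ± 0.26 (SD, n = 3 each), and Ptch1, the hedgehog receptor and a target of the pathway, 6.69 ± 2.20 against 8.63 ± 0.40. Ptch1 did not pass, and its difference of -1.94 was -0.76 without positive replicate 3, the dim array. As with mesenchymal genes, the list median in positive replicate 1 lay at -0.09 against the negative mean, compared with -0.88 and -1.48 in replicates 2 and 3. Without positive replicate 2 the list was not called (camera adjusted p = 0.0555, and 2.38e-06 to 0.437 over 26 alternatives).

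Tubercle patterning factors and Wnt response genes were lower by camera as lists, and both calls were lost at adjusted p = 0.285 with an estimated correlation. Relative to the negative mean, the patterning median was -0.18, -0.35 and -0.89 in positive replicates 1, 2 and 3, and the Wnt response median was -0.05, -0.56 and -0.84. The list of 5 prime Hox and patterning factors had a median of -0.41 over 22 members, with none past over all genes or adjusted over the list alone (camera adjusted p = 5.05e-05, and adjusted p = 0.285 with an estimated correlation). Tbx4 and Six2, transcription factors of limb and tubercle mesenchyme, differed by -2.11 (SE 0.67) and -1.92 (SE 0.53), whereas Hoxd13 and Isl1 differed by -0.02 (SE 0.27) and -0.15 (SE 0.37). None of these 4 genes passed the threshold. Wnt response genes and inhibitors had a median of -0.42 over 22 members (camera adjusted p = 0.0140, and adjusted p = 0.285 with an estimated correlation), led by the secreted antagonists Frzb at -1.86 (SE 0.51) and Dkk2 at -1.25 (SE 0.38). A further probe set of Frzb went the other way. Without negative replicate 3 or positive replicate 2 the Wnt list was not called (camera adjusted p = 0.0618 and 0.132, and 0.00496 to 0.285 over 26 alternatives). The ephrin and Eph receptor list was called in the 6 arrays (camera adjusted p = 0.0371, and adjusted p = 0.648 with an estimated correlation) with a median of -0.33 over 18 members, and array medians of 0.20, -0.28 and -0.65 in positive replicates 1, 2 and 3. It was not called without negative replicate 1 (0.0532), positive replicate 2 (0.119) or positive replicate 3 (0.592), and camera gave 0.00324 to 0.853 over 26 alternatives. In both lists no member passed over all genes or adjusted over the list alone.

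**Figure D3:**
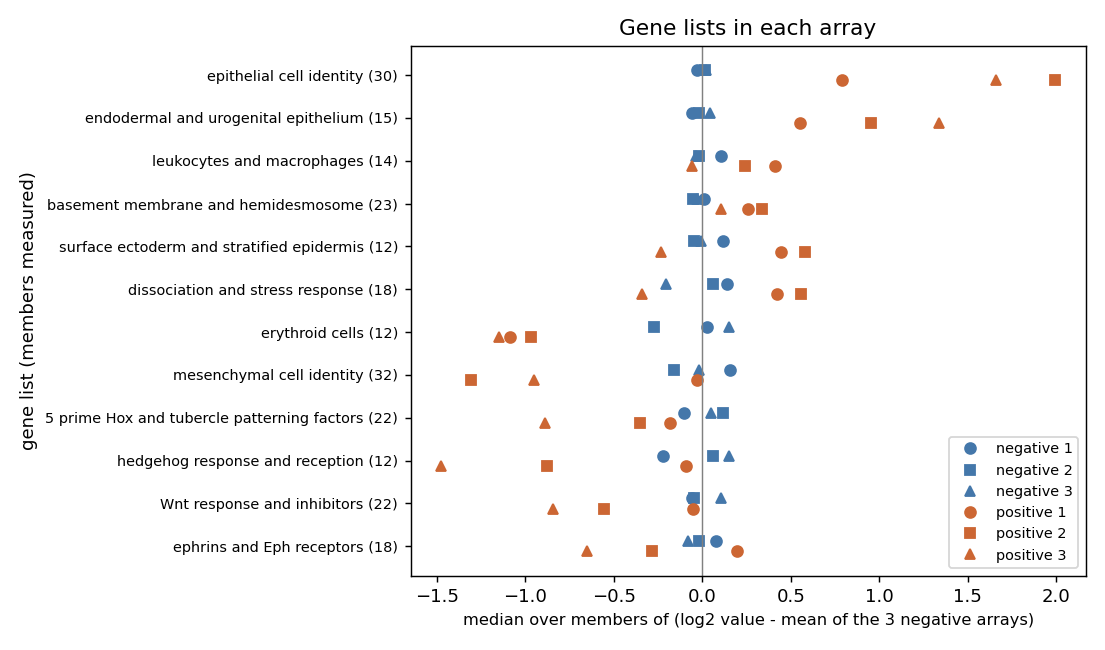
Median over the members of each gene list of the log2 value minus the mean of the 3 negative arrays (horizontal axis, log2 units), for the 12 lists called by camera with a preset correlation, with measured members in brackets; blue symbols are negative arrays and orange symbols positive arrays. For mesenchymal genes positive replicate 1 lies at -0.03 and replicates 2 and 3 at -1.31 and -0.95, while for erythroid genes the 3 positive arrays lie between -1.15 and -0.97.

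Erythroid markers were lower and leukocyte markers higher by camera, the latter not in every array. The erythroid list had a median of -1.09 over 12 members, with none past over all genes and 6 lower adjusted over the list alone (camera adjusted p = 4.33e-09, and adjusted p = 0.166 with an estimated correlation). Each positive array was low, with list medians of -1.09, -0.97 and -1.15 in replicates 1, 2 and 3. Leukocyte and macrophage markers were higher by camera (adjusted p = 0.00109, and adjusted p = 0.285 with an estimated correlation), with a median of 0.21 and 11 of 14 members positive. Their list medians against the negative mean were 0.41 and 0.24 in positive replicates 1 and 2 and -0.06 in replicate 3. None passed over all genes and 2 passed adjusted over the list alone, the complement genes C1qa and C1qb. In the 5 arrays 3 members were higher, C1qb at 1.46 (SE 0.25), C1qa at 0.80 (SE 0.17) and Csf1r, the macrophage growth factor receptor, at 2.07 (SE 0.31). A further probe set of Csf1r went the other way. The leukocyte list was not called without positive replicate 1 (camera adjusted p = 0.280, and 1.55e-13 to 0.285 over 26 alternatives).

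Genes that respond to cell dissociation were higher by camera (adjusted p = 0.0371, and adjusted p = 0.482 with an estimated correlation), with a median of 0.20 and 14 of 18 members positive. None passed over all genes or adjusted over the list alone. Junb, an immediate early gene, measured 5.11 ± 0.89 against 4.15 ± 0.09 (SD, n = 3 each), and the heat shock gene Hspa1b 6.84 ± 1.77 against 5.76 ± 1.59. Without positive replicate 3 the difference of Junb was 0.51 instead of 0.96, and that of Hspa1b 1.92 instead of 1.08, and neither gene passed. Relative to the negative mean, this list median was 0.42 and 0.56 in positive replicates 1 and 2 and -0.34 in replicate 3. Without negative replicate 3, positive replicate 1 or positive replicate 2 it was not called (camera adjusted p = 0.323, 0.304 and 0.268, and 0.000185 to 0.482 over 26 alternatives).

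The other 15 lists were not called by camera with the preset correlation. Among signalling lists the adjusted p was 0.0627 for the BMP and TGF-beta pathway, 0.274 for hedgehog ligands and release, 0.578 for Notch, 0.794 for Wnt ligands and for retinoic acid, and 0.921 for FGF. Among cell types it was 0.725 for endothelium, 0.767 for Schwann cells and melanocytes, 0.886 for skeletal muscle and 0.982 for neurons. It was 0.0895 for the mitotic cell cycle, 0.559 for sex chromosome transcripts, 0.578 for ribosomal proteins, 0.686 for hypospadias and steroid hormone genes and 0.904 for the apical ectodermal ridge of the limb. Besides Shh, which the hedgehog ligand list also holds, no member of these lists passed over all genes in the 6 arrays, and adjusted over the list alone only Shh and Gpc3 passed, both in the hedgehog ligand list. The BMP and TGF-beta list was called in 8 of 26 alternatives (lowest camera adjusted p = 0.00579). The mitotic cell cycle list was called in 4 of 26 (lowest camera adjusted p = 0.000364). In the neuron, limb ridge, hypospadias and ribosomal lists the median, the mean or the direction of the test differed in sign. Members with large differences that did not pass over all genes were Crabp2, a retinoic acid binding protein, at -2.54 (SE 0.79, and -1.65 without positive replicate 3), Gpc3, a glypican, at -2.05 (SE 0.61), and Eya1, a transcriptional cofactor, at -1.86 (SE 0.47). Positive differences that did not pass included Trp63, the transcription factor of stratified epithelia, at 2.06 (SE 0.53), Sp8 at 1.68 (SE 0.52), Wnt4 at 1.63 (SE 0.49) and the Notch target Nrarp at 1.32 (SE 0.45).

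Camera with its preset correlation thus called 12 of 27 lists, 6 higher and 6 lower in reporter-positive cells. With an estimated correlation it called none (lowest adjusted p = 0.158), with 4 lists at an unadjusted p under 0.05. Fry, which asks whether the members of a list move on balance in 1 direction, called 4 lists. The epithelial, endodermal and basement membrane lists were higher and the erythroid list lower, each at an adjusted p of 0.0192. In the 5 arrays fry called none (adjusted p = 0.0649 for each of these 4 lists), with 9 lists at an unadjusted p under 0.05.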

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

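This part reports probe sets without a gene name here, which the comparisons of genes left out, and the fit in which they passed was chosen for emphasis only after the data were seen. In the 5 arrays without positive replicate 3, 5 of 4298 tested probe sets without a name passed an adjusted p of 0.05 (limma), 3 higher and 2 lower in reporter-positive cells. The log2 differences of the higher ones were 2.56 (SE 0.37), 2.07 (SE 0.34) and 1.61 (SE 0.27), and those of the lower ones were -1.90 (SE 0.35) and -1.92 (SE 0.36). At an unadjusted p under 0.05 limma counted 207. In the 6 arrays none of 4262 passed (limma), with 111 at an unadjusted p under 0.05. Their transcripts were not identified, and no explanation was tested.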

How the results depend on the processing

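Array weights, a trimmed mean, and the block or estimated correlation without positive replicate 3 were chosen after seeing the data. Shh and Krt8 stayed higher in all 23 alternatives (log2 2.77 to 7.11 and 2.55 to 5.76), past the threshold in 16 each. Values as deposited gave 0 genes, 0 by 2-fold (limma, 401 at an unadjusted p under 0.05, median of all genes -0.48), with Shh at 3.12 and uncalled genes reversed: Chrna1 -0.0232, Egfl7 -0.15, Erbb3 -0.0606, Rplp0 -1.37, Scube3 -0.65, Uty -0.21 and Xist -1.04. Median centring gave 33 and 6 by 2-fold (median -0.28), neither Shh nor Krt8 among them, with Shh at 3.32 and reversed Rplp0 -1.17, Scube3 -0.45, Uty -0.0210 and Xist -0.85. The stricter filter gave 6 and 6, a pseudocount of 1 gave 7 and 7 (median -0.16), and a pseudocount of 64 gave 0 and 0 (663 unadjusted, Shh 3.40). The mean of probe sets gave 0 and 0 (775 unadjusted, Shh 2.77), and the most variable probe set gave 5 and 5 (Xist reversed, -0.71). Fits without trend and with a trimmed mean gave 3 each. Array weights gave 480 (255 higher, 225 lower) and 328 (Scube3 reversed, -0.0832). The pool block without positive replicate 3 gave 562 (283 higher, 279 lower) and 446, with Mcm3 0.0573, Scube3 -0.0650 and Uty -0.0453 reversed, and there negative replicate 3 is alone in its block. Leaving out an array or a pool size gave 0 to 84 genes, 0 to 80 by 2-fold, and Shh at 4.58 to 5.50. The count was 0 without each single negative array (289, 260 and 597 unadjusted for replicates 1, 2 and 3), 22 without positive replicate 1, 27 without replicate 3 and 84 without positive replicate 3. Reversed in these were Uty (-0.11 to 0.25), Scube3 (-0.15 to 0.89), Erbb3 (-0.00454 to 0.89), Ets1 (-2.25 to 0.17) and Mcm3 (-1.07 to 0.0583). Of 27 lists camera called 7 to 13 in these, 0 with an estimated correlation, with or without positive replicate 3, and fry 4. The epithelial, endodermal, basement membrane and erythroid calls were lost under the estimated correlation and, outside these alternatives, under fry without positive replicate 3 (adjusted p = 0.0649 each). No called list reversed under camera or 6-array fry. Fewer arrays were tested in leave-one-out fits, and for the other changes the cause was not tested. Signal over background limits dim genes most in positive replicate 3.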

Other observations

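The tests of array signal, of mesenchymal transcripts, of red cell loss and of macrophage genes against background were chosen only after the result was seen, and so were the genes named here. In the 5 arrays without positive replicate 3, 3 genes known from platelets were among the 77 higher ones (limma), Pf4 at 2.33 (SE 0.29), Ppbp at 1.34 (SE 0.22) and Tubb1 at 1.23 (SE 0.23). No platelet list was tested, and in positive replicate 3 Pf4 and Ppbp were at 4.40 and 4.02, within the negative range or below it, while Tubb1 was at 4.67, above the negatives. The epithelial transcription factor Klf5 was higher at 2.00, the posterior Hox gene Hoxb13 at 1.61 and the Notch target Hes1 at 1.77. In the 6 arrays Hoxb13 and Hes1 were at 1.06 and 1.12 and did not pass, and Hes1 in positive replicate 3, at 4.70, lay within the negative range. Hspa1b was at 7.60 and 8.78 in negative and positive replicate 1 and 4.83 to 6.41 in the other 4 arrays, whereas another heat shock gene, Hspb1, was at 4.60 to 5.27 in negative and 6.49 to 8.40 in positive arrays. The Y-linked gene Eif2s3y was 5.60 and 5.93 in replicate 2 and 4.29 to 4.95 elsewhere. Hspa1b and Eif2s3y were thus each high in both arrays of the same replicate number, as a shared pool could give. They were picked after their values were seen, so they do not settle it.

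Positive replicate 3 carried little transcript signal, but its hybridization controls were 1.14 times the mean of the other arrays, which argues against a failed hybridization or scan. Its Actb ratio of 3 prime to 5 prime signal, 10.3, lay above 4 of the 5 others (4.23 to 10.8), and its Gapdh ratio, 7.35, within their range of 5.83 to 9.27. Both rested on 5 prime signals of 2.28 and 3.47 near the background of 1.12, so degraded RNA stayed open. The pool of 2 embryos had the lowest median signal in 2 of 2 groups, so little labelled target from the pool of 2 embryos may explain it, although chance gives this in 1 of 9 cases. No biological explanation was tested.

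Mesenchymal transcripts stayed high in positive replicate 1, at a median of 0.962 of the negative level over 17 bright list members (quartiles 0.779 to 1.17), against 0.150 in positive replicate 2. Erythroid members stood at a median share of 0.0296 in replicate 1 (upper quartile 0.298, 7 members). For that array this argues against carry-over of all reporter-negative cells in equal shares. In positive replicate 2 the erythroid median share was 0.110 (quartiles 0.078 to 0.321), within the mesenchymal quartiles of 0.064 to 0.368. Equal shares therefore stayed open for replicate 2. Epithelial members that were bright in positive replicate 2 were lower in replicate 1 by a median of -1.26, in 17 of 17, so mesenchymal cells in the sorted fraction may be a source. The members were picked for brightness in replicate 2, which favours this direction, and the sort for reporter fluorescence should have removed such cells.

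Macrophage transcripts were higher in positive replicates 1 and 2, with list medians of 0.41 and 0.24 against the negative mean, but not in replicate 3 (-0.06). Only 3 of 14 list members passed in the 5 arrays, and the list call in the 6 arrays was lost with an estimated correlation (camera adjusted p = 0.285). The mesenchymal median was -0.58 and the endothelial median 0.09 in the 5 arrays, against 0.46 for leukocytes. In positive replicate 1 mesenchyme was not lowered, with a list median of -0.03. The sort should lower each of these cell types, by amounts not known here. These values therefore cannot decide the matter, and a rise of other cell types through red cell loss stayed open. In a second macrophage list, which shared no tested gene with the other lists, 7 of 17 measured members (Ctss, Fcrls, Lgmn, Stab1, Cd14, Fcgr3 and Itgb2) lay above all negatives in both positive arrays with signal, and 0 below (chance share 0.1, binomial p = 0.000784). Only Ctss and Fcrls lay above the negatives by wide margins, 0.94 and 0.53, while the other 5 did so by 0.0293 to 0.151 near background, and 6 of the 7 exceeded background in both arrays (binomial p = 0.00467). Over all genes in the 5 arrays the groups did not overlap, in either direction, for 24.6%, where chance gives 20%. A reference of 0.1 for 1 direction may therefore be low. The second list was read on the same arrays that gave the pattern, and Ctss was already among the 84 genes, so it is not independent support. Macrophages in the sorted fraction may be a source, although the sort should have removed them, and the binomial test treats genes as independent.

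The 6 samples make 10 splits, so the share of splits with as many genes, 1 of 10, is never under 0.1. The real split gave 2 genes and the highest other gave 0 (limma).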
